A study of Mus musculus with 6 samples.

How the data were processed

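Lung RNA of 3 mouse strains was profiled on 6 Affymetrix arrays, 1 control and 1 smoked array for each of C57, DBA and ICR. Per the labels' protocols, total RNA was extracted with Trizol, reverse-transcribed from an oligo(dT) primer carrying a T7 promoter, and transcribed into biotin-labelled cRNA. The titles number each sample as mouse 1 of its group, and whether an array holds 1 mouse or a pool is not given in the sources used here. Strains are named only as in the labels.

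The deposited values are the probe set intensity on a linear scale, from 0.0305 to 10579, with 1 value for each of 12488 probe sets on every array. The summary method, software and scaling used by the authors are not given in the sources used here. Array medians of the log2 values spread over 1.45, more than the limit of 0.1 set for using the values unscaled. This does not show whether the authors had scaled the arrays on another measure. No pair of arrays was a duplicate. Signal over background differed between arrays, and the ICR smoked array had the lowest median. Precision is limited by the number of arrays.

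The following was fixed before the data were examined: the scale, the rule for normalization, the filter, the tests, 47 gene lists and the rule for naming genes. Values were transformed as log2 of the value plus 8.05, the 20th percentile of all values, and quantile normalized between arrays. Where a gene read below that constant on one side of a comparison, the fitted size of its difference depends on the constant. The 66 control probe sets were left out, and probe sets with a mean above the 40th percentile were kept, which left 7453. Of all probe sets, 10855 had 1 gene symbol, 396 several and 1237 none. Symbols of 10839 were matched by gene identifier to a mouse reference annotation, and none changed. Chromosomes come from that annotation. Genes were represented by the probe set with 1 symbol and the highest mean, which gave 8251 genes, 5735 after the filter.

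The smoke effect was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend), with strain as a block, so that the 3 strains gave 3 pairs and 2 residual degrees of freedom. Strains were compared in the same fit. Whether the response of 1 strain differed from that of the other strains was fitted with an extra smoke effect for that strain, which leaves 1 residual degree of freedom and assumes that the single pair varies like the others. All tests were 2-sided with Benjamini-Hochberg adjustment over the probe sets kept, and a probe set is called, or said to have risen or fallen, at an adjusted p below 0.05. Within a strain, probe sets at least 2-fold different were counted with no test.

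Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, for the 45 lists with at least 4 genes tested, with adjustment over lists. List medians use all measured genes. Members were also adjusted over the list alone.

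Named genes were, for the shared smoke effect, the 15 largest increases and 10 largest decreases that passed, with open places filled by genes of the same direction in all strains ranked by their smallest difference. For each strain the 6 largest differences in each direction were taken, for each comparison of strains the 4 largest, and for each response the 5 largest. Gene list members were named as examples. Hc was named as a member of a fixed list after its values were seen, as were the examples from the immunoglobulin, clock, heat shock and muscle genes and the extra genes shown on the plot of strain genes.

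The tests were tried on simulated data in which 210 of 7453 probe sets were changed. For each probe set the simulated spread was the same on all arrays and came from the shared smoke fit. The shared smoke test recovered 57.1% of 2-fold and 100% of 4-fold changes, with 6 calls on unchanged probe sets. The test of the DBA response recovered 7.14% of 2-fold, 62.9% of 4-fold and 98.6% of 8-fold changes, with 38 calls on unchanged probe sets. The tests of the C57 and ICR responses made 7 and 10 such calls and recovered 25.7% and 28.6% of 4-fold changes, and 81.4% and 75.7% of 8-fold changes.

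Alternatives were another pseudocount, no filter or a stricter one, no scaling or scaling to a common median, a variance prior without trend or robust, no strain block, other fold thresholds, and each pair or array left out in turn. Alternatives chosen after the data were seen were the variance prior of the shared smoke fit for the response contrasts and the exclusion of neutrophil, monocyte, B cell, liver and immunoglobulin genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.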

Results

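Gene expression was measured in whole lung of 3 kinds of mice, labelled C57, DBA and ICR (ICR is an outbred stock), with and without exposure to cigarette smoke. Smoked mice received the smoke of 3 cigarettes daily on 5 days of each week for 4 weeks. The title of the series asks about resistance or sensitivity of the lung to smoke, but no label says which strain is which. There were 6 Affymetrix arrays, 1 control and 1 smoked array per strain, so no group within a strain had replicates, and the 3 strains served as the replicates of the smoke effect (n = 3 pairs). Each array held 12488 probe sets, of which 7453 passed the filter on low signal. Median deposited intensity was 60.3 for C57 control, 60.6 for C57 smoked, 68.9 for DBA control, 85.0 for DBA smoked, 52.5 for ICR control and 26.0 for ICR smoked. The ICR smoked array also had the highest 3' to 5' signal ratios of the control transcripts, 4.75 for beta-actin and 2.39 for Gapdh, against 1.46 to 2.75 and 0.952 to 1.69 on the 5 other arrays. The beta-actin ratio was 2.75 and 2.51 on the C57 control and smoked arrays, 1.46 and 1.66 in DBA, and 1.63 for ICR control. After normalization the arrays of a strain correlated at 0.972 for C57, 0.950 for DBA and 0.931 for ICR across probe sets, and arrays of different strains at 0.880 to 0.929. The number of arrays limits the precision of every value given here.

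The first comparison asked what smoke changed in the lungs of all 3 strains. In every strain 3 genes of xenobiotic metabolism rose with smoke. Cyp1a1 (chromosome 9), the cytochrome P450 that oxidizes polycyclic aromatic hydrocarbons and is induced through the aryl hydrocarbon receptor, rose 19.3-fold on average (log2 4.27, SE 0.28, adjusted p = 0.000796; log2 5.12 in C57, 3.69 in DBA, 4.00 in ICR). Its deposited intensity went from 58.8 to 2552 in C57, from 16.9 to 385 in DBA and from 36.1 to 368 in ICR. Cyp1b1 (chromosome 17), a related P450, rose 4.00-fold (log2 2.0, SE 0.24, adjusted p = 0.0454; log2 2.26 in C57, 2.33 in DBA, 1.41 in ICR). Aldh3a1 (chromosome 11), an aldehyde dehydrogenase that clears reactive aldehydes, rose 3.67-fold (log2 1.87, SE 0.22, adjusted p = 0.0454; log2 1.42, 2.40 and 1.80 in the same order). These were the 3 probe sets called by limma, with none lower, and 122 had an unadjusted p below 0.05. Over 12 alternatives Cyp1a1 was still called in 10, Aldh3a1 in 7 and Cyp1b1 in 5.

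Further genes with the same direction in all 3 strains did not pass the test, each at an adjusted p near 1. Among those with higher values on the smoked arrays were Nqo1, a quinone reductase (log2 1.24, SE 0.30), Gpx2, the epithelial glutathione peroxidase (0.94, SE 0.20), Srxn1, which repairs oxidized peroxiredoxins (0.71), Akr1b8, an aldo-keto reductase (0.68), and Ces1g, a carboxylesterase (1.31, with 2.51 in DBA and 0.37 in ICR). Kdr, the receptor for vascular endothelial growth factor, and Tgfb2, a growth factor, had values of 0.44 and 0.50. Lower values were found for Il1b, the inflammatory cytokine interleukin 1 beta (-0.79), Arg2, a mitochondrial arginase (-0.77), F5, coagulation factor 5 (-0.74), and the muscle genes Acta1 (-1.11) and Myoz1 (-1.16). For Nectin3, an adhesion molecule, the probe sets went opposite ways in every strain, one lower (log2 -1.05) and the other higher (0.32). The same direction in all 3 strains was shared by 1314 probe sets, or 17.6%, against 25% for 3 unrelated differences. A change of at least 2-fold in every strain was seen for 3 probe sets upward and 0 downward by this direct count without a test.

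The count of 3 rested on the strains included: without the C57 pair limma called 11 probe sets, without the DBA pair 5, and without the ICR pair 0, when Cyp1a1 had an adjusted p of 0.176. With the C57 pair left out, 7 of the 11 were lower, among them the neutrophil genes Ngp, S100a8, S100a9 and Csf3r, which were higher on the DBA control array than on the DBA smoked array (for Csf3r by log2 values of -2.56, -2.55 and -0.58 at its 3 probe sets, smoked minus control). It fell to 1 without the filter on low signal or without the mean trend in the variance, and to 0 without strain as a block. Without scaling between arrays, where the median over all probe sets was -0.21, limma also called 3, but 1 higher and 2 lower.

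**Figure D1:**
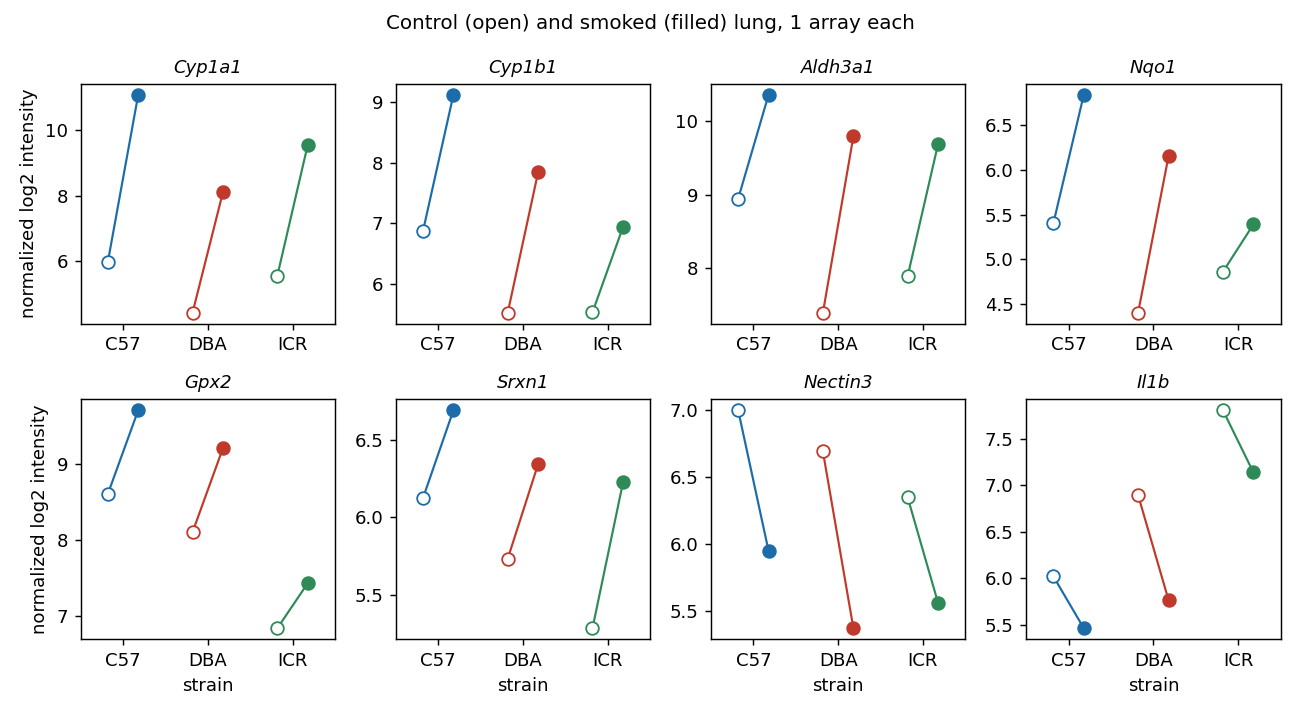
Normalized log2 intensity of 8 genes on each array, with control arrays as open and smoked arrays as filled circles, joined within each strain (1 array per point, each panel with its own axis). Cyp1a1, Cyp1b1 and Aldh3a1 passed the test for all 3 strains (log2 4.27, 2.0 and 1.87), while Nqo1, Gpx2, Srxn1 and Il1b had the same direction in each strain without passing it, as did the probe set plotted for Nectin3, whose other probe set went the opposite way (0.32).

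Lists of aryl hydrocarbon receptor and NRF2 targets were called higher with the preset correlation but not with an estimated one (adjusted p = 0.825 for each), and their medians in ICR, 0.05 and 0.02, lay at percentiles 56.6 and 45.0 of random lists. Of the 8 aryl hydrocarbon receptor targets tested, 3 rose and 5 did not pass, and Nqo1 (adjusted p = 0.00515) made 4 when adjusted over the list alone. The list median was 0.53 in C57, 1.10 in DBA and 0.05 in ICR, and the list was called higher by camera (adjusted p = 7.19e-10; adjusted p = 0.825 with an estimated correlation). None of the 26 NRF2 antioxidant genes tested passed over all genes or when adjusted over the list alone, but 11 had higher values in all 3 strains and 1 lower, among them Gsta2 (log2 0.69), Gsr (0.48), Txnrd1 (0.44) and Gclm (0.43), which make or use glutathione and thioredoxin. Their median was 0.15, 0.46 and 0.02 in C57, DBA and ICR (camera adjusted p = 3.96e-06; adjusted p = 0.825 with an estimated correlation). The 13 other antioxidant enzymes were not called as a list (adjusted p = 0.302), although Gpx2 passed when adjusted over the list alone (adjusted p = 0.0130).

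Of 4 lists for lung epithelium 2 were called higher, and 3 leukocyte lists were called lower, with no member passing over all genes. Alveolar type I cell markers (5 genes, medians 0.14, 0.17 and 0.16 in C57, DBA and ICR, with Emp2 at 0.52 and Pdpn at 0.25) and club and goblet cell markers (7 genes tested, medians 0.04, 0.21 and 0.12, with the antimicrobial lectin Reg3g at 0.62) each had a camera adjusted p of 0.0386 (adjusted p = 0.825 with an estimated correlation), and were still called in 5 and 4 of 10 alternatives. Alveolar type II cell markers (medians 0.05 in C57, -0.16 in DBA and 0.11 in ICR; adjusted p = 0.302) and ciliated cell markers (medians -0.32, -0.02 and 0.48; adjusted p = 0.761) were not called. Neutrophil genes (10 tested) were called lower (adjusted p = 2.67e-08; adjusted p = 0.825 with an estimated correlation), with medians of -0.08 in C57, -2.15 in DBA and -0.29 in ICR, so the DBA pair set the list's value. Dendritic cell and MHC class II genes (13 tested; adjusted p = 0.0137, or adjusted p = 0.885 with an estimated correlation) and NK cell genes (4 tested; adjusted p = 0.0461, or adjusted p = 0.825 with an estimated correlation) were likewise lowest in DBA, with medians of -0.47 and -0.66. Their medians were -0.003 and 0.32 in C57, and 0.07 and -0.007 in ICR. Without the DBA pair 0 lists were called lower, so the calls of these leukocyte lists rested on that pair.

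Glucocorticoid-responsive genes were also called lower (13 tested, medians -0.12, -0.22 and 0.15; adjusted p = 0.0123, or adjusted p = 0.825 with an estimated correlation). Zbtb16, a transcription factor induced by glucocorticoids, contributed most in C57, at log2 -2.70 against -0.22 in DBA and 0.48 in ICR. Skeletal muscle genes, which a lung sample holds only by way of adjoining muscle, had medians of -0.47, -0.50 and 0.30 in C57, DBA and ICR (10 tested; adjusted p = 0.000831, or adjusted p = 0.854 with an estimated correlation), with Acta1 and Myoz1 lower when adjusted over the list alone (adjusted p = 0.0384 for each). Their median thus had the opposite sign in ICR.

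The 11 acute inflammation cytokines and chemokines tested were not called as a list (adjusted p = 0.658). Adjusted over the list alone, Cxcl5, a neutrophil-attracting chemokine, was higher and Il1b lower (adjusted p = 0.0364 for each), but Cxcl5 had log2 values of 2.18 in C57, 2.26 in DBA and 0.12 in ICR. Lists for matrix proteases (adjusted p = 0.750), elastin and collagen (0.288), interferon response (0.887), heat shock (0.478), p53 (0.622), cell cycle (0.887) and apoptosis (0.151) were not called. In all, 9 of 45 lists were called, 4 higher and 5 lower, 0 with an estimated correlation. Over all genes 3 list members passed, and 9 when adjusted over the list alone. Without the C57 pair camera called 14 lists (3 higher, 11 lower), without the DBA pair 2 (2 higher, 0 lower) and without the ICR pair 10 (4 higher, 6 lower).

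**Figure D2:**
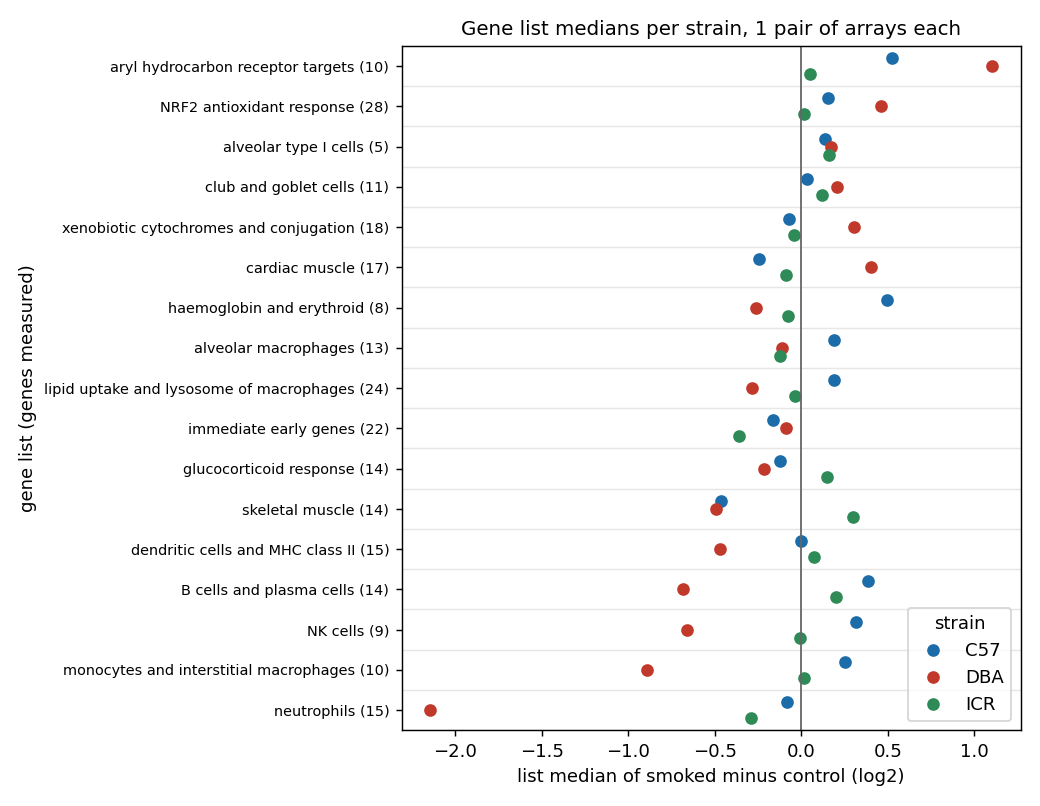
Median log2 difference between smoked and control lung over the measured genes of 17 gene lists (number measured in parentheses), with 1 point per strain from 1 pair of arrays. Aryl hydrocarbon receptor and NRF2 targets lie above 0 in C57 and DBA, at 0.53 and 1.10 and at 0.15 and 0.46, and the neutrophil list lies at -2.15 in DBA.

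The next comparison asked how the lungs of the 3 strains differed whatever the exposure, from 2 arrays per strain. DBA and C57 differed at H2-Ea and in skeletal muscle and clock genes. H2-Ea, an MHC class II chain that presents antigen, was higher in DBA (adjusted p = 1.72e-05), with deposited intensities of 1594 and 1450. In C57 it read 1.96 and 1.83, below the constant of 8.05 added before taking logs, so its fitted log2 difference of 6.96 (SE 0.29) depends on that constant and ran from 5.24 to 7.93 over the alternatives. Clca1, a secreted product of goblet cells (log2 4.17, SE 0.47, adjusted p = 0.00341), Pam, which amidates peptide hormones (3.78, SE 0.37, adjusted p = 0.00223), and Serpina1b, an antitrypsin (3.65, SE 0.53, adjusted p = 0.00997), were higher in DBA too. Serpina1b, a gene abundant in liver, read 428 on the DBA control array and 1363 on the DBA smoked array, on which Alb and Mup3 were also high, and was still called in 10 of 14 alternatives (2.57 to 4.73). Hc, complement component 5 and a member of the list of known strain differences, was lower in DBA by log2 -2.21 (adjusted p = 0.00186). In all, limma called 129 probe sets, 65 higher and 64 lower in DBA.

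C57 lungs held more skeletal muscle message. Of 10 skeletal muscle genes tested, 5 were lower in DBA and 5 were not called. The lower ones were the fast muscle genes Myh1 (log2 -3.85, SE 0.51), Acta1 (-3.84, SE 0.38), Tnnc2 (-2.95, SE 0.32), Tnnt3 (-2.71, SE 0.32) and Atp2a1 (-2.34, SE 0.29). The list median was -2.11 (camera adjusted p = 3.91e-14; adjusted p = 0.553 with an estimated correlation). Markers of oesophagus and tracheal epithelium moved with it, at a median of -1.83 (adjusted p = 0.000156; adjusted p = 0.553 with an estimated correlation), with 1 of 4 tested called. The metallothioneins Mt1 and Mt2, which bind zinc and copper, were lower in DBA by log2 -1.29 and -1.19, while 4 of 13 clock genes were higher: Dbp (3.28), Nr1d1 (2.97), Nr1d2 (1.75) and Per3 (1.5). The clock list was called (adjusted p = 0.00207; adjusted p = 0.553 with an estimated correlation). Hour of collection, dissection and RNA quality were not modelled, and 2 arrays per strain cannot part them from strain.

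ICR differed from C57 at 171 probe sets, 69 higher and 102 lower in ICR. Hspa1b, an inducible heat shock protein 70 (log2 3.01, SE 0.29, adjusted p = 0.00141), Pam (2.99, SE 0.37), Dbp (2.79, SE 0.36) and H2-Ea (2.65, SE 0.29) were higher; C57 read Dbp at 5.46 and 6.56, below the added constant, as for H2-Ea. Acta1 (log2 -6.10, SE 0.38, adjusted p = 0.000265), Myh1 (-4.41, SE 0.51) and Mt4, a metallothionein of stratified epithelia (-4.14, SE 0.64), were lower. ICR read Myh1 at 2.26 and 5.01 and Mt4 at 4.94 and 2.44, below the added constant, and the fitted differences ran from -5.41 to -3.08 and from -5.10 to -2.81 over the alternatives, in which Mt4 was still called in 8 of 12. In all, 5 of 10 skeletal muscle genes were called lower, with a list median of -2.51 (camera adjusted p = 2.10e-13; adjusted p = 0.492 with an estimated correlation). Krt13, a keratin of the oesophagus list, was lower by -3.45. The called Actb probe set (-4.86, SE 0.46) reads Actb at 7.31 and 31.2 in ICR and 1270 and 1097 in C57, while the 3' beta-actin control probe set read 6064 and 2736 in ICR and 3272 and 4552 in C57. Whether strain sequence differences under the probes set the Actb signal in ICR was not tested. Of the probe sets called in DBA against C57, 51 were called in the same direction in ICR against C57, but both contrasts share the C57 arrays, so the overlap was not tested.

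Between ICR and DBA limma called 87 probe sets, 38 higher and 49 lower in ICR. ICR had more Hspa1b (log2 3.62, SE 0.29, adjusted p = 0.000591) and Hspa1a (2.15, SE 0.23), so that 2 of 18 heat shock genes were called, with a list median of 0.38 (camera adjusted p = 0.000121; adjusted p = 0.670 with an estimated correlation). Phlda1 (2.49, SE 0.25), Thumpd1 (2.46, SE 0.26) and Gm15772 (2.32, SE 0.18) were also higher. H2-Ea (-4.30, SE 0.29), Clca1 (-4.24, SE 0.47), Actb (-4.22, SE 0.46) and Ctse, an aspartic protease (-3.27, SE 0.29, with -2.91 and -0.21 at its other probe sets), were lower, but the 3' beta-actin control probe set read 7168 and 7283 in DBA against 6064 and 2736 in ICR. The immediate early genes were higher as a list in ICR than in DBA (median 0.55, 2 of 20 called; adjusted p = 1.30e-05, or adjusted p = 0.670 with an estimated correlation).

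Camera called 14, 16 and 11 of 45 lists in DBA against C57, ICR against C57 and ICR against DBA, and 0 with an estimated correlation, whose smallest adjusted p values were 0.553, 0.492 and 0.670. Without the filter on low signal the 3 counts of probe sets were 66, 44 and 38. Without scaling between arrays the balance of directions changed: 64 higher and 21 lower in DBA against C57, 7 higher and 138 lower in ICR against C57, and 4 higher and 257 lower in ICR against DBA, with medians over all probe sets of 0.14, -0.73 and -0.89. Leaving out an array keeps the same probe sets but leaves fewer residual degrees of freedom and a newly fitted variance prior. Counts can therefore move even for an array outside the contrast. The counts also depended on single arrays: DBA against C57 rose to 244 without the C57 smoked array and 298 without the DBA smoked array. ICR against C57 was 32 without the ICR control array, 63 without the ICR smoked array, 95 without the C57 control array, 513 without the DBA control array and 517 without the DBA smoked array. ICR against DBA was 12 without the ICR control array and 15 without the ICR smoked array, 145 and 218 without the DBA control and smoked arrays, and 220 and 218 without the C57 control and smoked arrays.

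**Figure D3:**
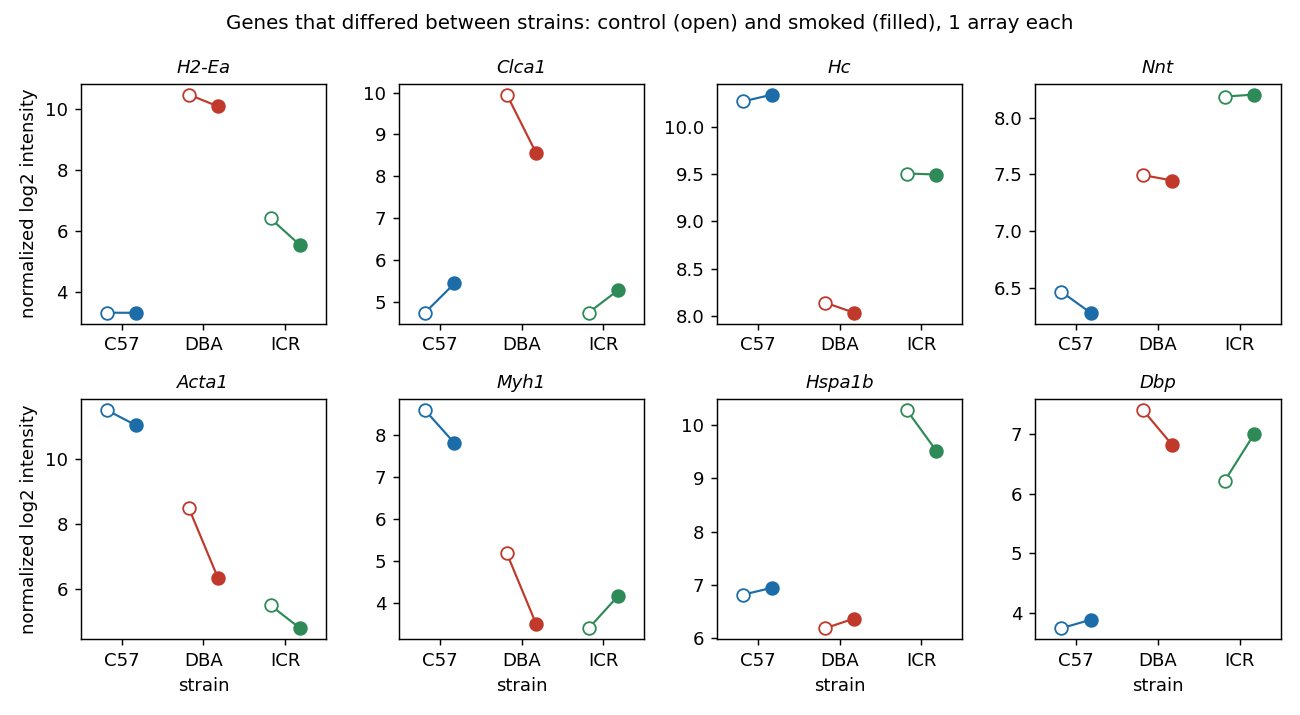
Normalized log2 intensity of 8 genes that passed the test in at least 1 comparison of strains, with control arrays as open and smoked arrays as filled circles, joined within each strain (1 array per point, each panel with its own axis). H2-Ea is higher in DBA than in C57, where it lies below the added constant, Acta1 is higher in C57 than in ICR, and Hspa1b is higher in ICR than in C57 by 3.01.

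The question of sensitivity was addressed by asking whether the pair of 1 strain differed from the pairs of the other strains. In the DBA pair, the difference between the smoked and control arrays was lower than in the C57 and ICR pairs for 6 neutrophil genes and 10 immunoglobulin probe sets, and higher for Alb, Mup3 and the antitrypsin genes Serpina1b and Serpina1e. With 1 pair per strain, a response of the strain cannot be separated from an unusual sample. Ngp and Camp, antimicrobial granule proteins of neutrophils, differed by log2 -6.97 (SE 0.70, adjusted p = 8.19e-16) and -5.21 (SE 0.55, adjusted p = 7.07e-15), and S100a8 and S100a9, the calprotectin chains, by -4.71 (SE 0.49) and -4.11 (SE 0.51). Ifitm6, a membrane protein of myeloid cells, differed by -3.98 (SE 0.57). Alb, serum albumin, differed by 6.62 (SE 0.60, adjusted p = 1.84e-18), Mup3, a major urinary protein, by 6.49 (SE 0.69), and the antitrypsins Serpina1e and Serpina1b by 2.65 (SE 0.54) and 2.05 (SE 0.54), while Rangrf, a nuclear transport factor, differed by 2.62 (SE 0.71). Limma called 53 probe sets, 10 higher and 43 lower, a balance that depended on the processing.

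The intensities located these differences on single arrays. S100a8 read 6766 on the DBA control array and 242 on the DBA smoked array, against 400 and 376 in C57 and 1449 and 471 in ICR. Ngp read 2551 on the DBA control array and at most 35.0 on the 5 others, in part below the added constant, so its fitted difference ran from -7.47 to -5.68 over the alternatives. Alb read 1455 on the DBA smoked array and at most 98.7 elsewhere, and Mup3 732 against at most 51.3 (fitted difference 4.52 to 7.53). Of 10 neutrophil genes tested, 6 were called lower in DBA and 4 were not called, and 10 of the 43 lower probe sets were immunoglobulin genes. Over the 28 immunoglobulin probe sets the median difference was -1.56 in DBA, 0.58 in C57 and -0.25 in ICR. Monocyte genes (10 measured, median -0.89 in DBA, 0.25 in C57) and B cell genes (14 measured, median -0.69 in DBA, 0.39 in C57) lay in the same direction in DBA with 0 called in the limma contrast, in which 294 of all probe sets had an unadjusted p below 0.05.

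This contrast had 1 residual degree of freedom and borrowed its variance from other genes. The borrowed variance counted as 194 degrees of freedom, and as 36.7 in the same contrast for C57. The SE and p values of these contrasts thus rest mostly on the spread of other genes. They do not measure how the named gene varies between animals. With the variance prior of the fit to all 3 strains, chosen after the data were seen, 9 probe sets were called (4 higher, 5 lower). On simulated data with changes of at most 8-fold, that setting recovered 0 of 210 changed probe sets and made 0 calls on unchanged ones. It is thus a strict setting, and loss of a call under it does not show that the call was false. Larger changes were not simulated. There were 8 calls for arrays scaled to a common median (4 higher, 4 lower), 7 without scaling (5 higher, 2 lower), 9 without the filter (5 higher, 4 lower), 25 with a stricter filter (3 higher, 22 lower) and 32 with a smaller pseudocount (6 higher, 26 lower). Of the named genes, Rangrf was still called in 1 of 8 alternatives, Serpina1b in 3 of 9, Serpina1e in 5 of 9 and Ifitm6 in 5 of 8, while Alb and Mup3 were called in 8 of 8 and Ngp in 7 of 7. On simulated data the test as reported called 38 unchanged probe sets.

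**Figure D4:**
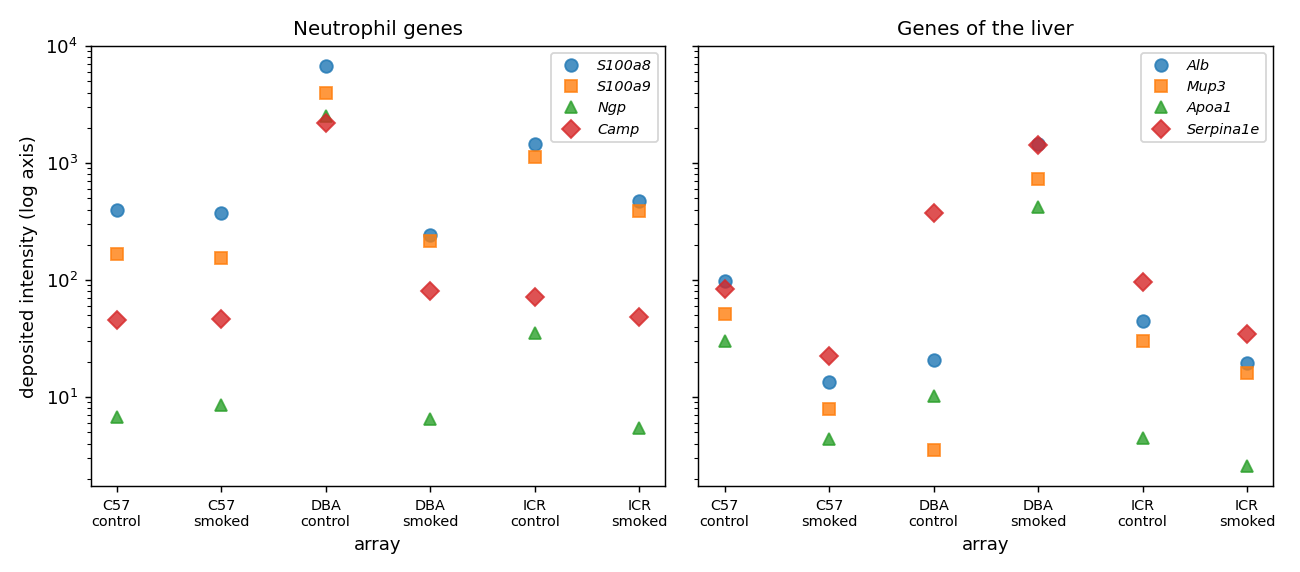
Deposited intensity, on a log axis, of 4 neutrophil genes (left) and 4 genes of the liver (right) on each of the 6 arrays, 1 point per gene and array. S100a8 stands at 6766 and Ngp at 2551 on the DBA control array, and Alb at 1455 and Mup3 at 732 on the DBA smoked array.

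In the C57 pair, the difference between the smoked and control arrays was higher than in the other pairs for 3 immunoglobulin probe sets, Chil3 and Lcn2, and lower for Zbtb16 and Alb, again from 1 pair. Zbtb16 differed by log2 -2.83 (SE 0.51, adjusted p = 0.00401), with a C57 difference of -2.70. Chil3, a chitinase-like protein of alveolar macrophages, differed by 2.86 (SE 0.54, adjusted p = 0.00923), from 1.38 in C57, -2.63 in DBA and -0.33 in ICR. Lcn2, a siderophore-binding protein of neutrophils and epithelium, differed by 2.87 (SE 0.59), from 1.36, -2.55 and -0.46 in the same order, but its other probe set, of lower signal, gave -0.43, from -0.26, -0.20 and 0.55. Igkv6-14 and Igkv6-23, immunoglobulin light chain genes, differed by 3.56 (SE 0.74) and 2.35 (SE 0.52), and Alb by -4.79 (SE 1.02). For each of these genes except Zbtb16 the DBA difference had the opposite sign to that of C57. Over the alternatives the call was kept by Igkv6-23 in 2 of 9, Igkv6-14 and Alb in 3 of 8, Lcn2 and Chil3 in 4 of 9 and Zbtb16 in 5 of 9. Limma called 10 probe sets, 7 higher and 3 lower. The count was 0 without the filter, 0 without scaling between arrays, 0 without the mean trend in the variance, 2 with a robust variance prior, 4 with a stricter filter, and 36 with arrays scaled to a common median, and 0 with the variance prior of the fit to all strains, a setting chosen after the data were seen that recovered 0 of 210 simulated changes.

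In ICR no probe set passed. Limma called 0, with 1067 at an unadjusted p below 0.05 and a smallest adjusted p of 0.302. On simulated data this test recovered 0% of 2-fold, 28.6% of 4-fold and 75.7% of 8-fold changes. For each probe set the simulated arrays shared 1 spread, while the real log2 differences had an SD of 0.544 in ICR, 0.461 in DBA and 0.345 in C57. Recovery in the real ICR contrast may therefore be lower, and Usp22, at log2 -3.25, did not pass. The count of 0 thus does not show that the ICR pair was like the others, whatever the size of the change. Among the largest positive values of the contrast were Camp (log2 2.89, SE 1.93), Sod1, the cytosolic superoxide dismutase (2.49, SE 0.35), and Ctrb1, a pancreatic protease precursor (2.41, SE 0.36). Among the largest negative values were Usp22, a ubiquitin protease (-3.25, SE 0.42), Rangrf (-3.03, SE 0.69) and Nr3c1, the glucocorticoid receptor (-2.44, SE 0.53). For Camp the value came from the DBA pair (-4.98), since the ICR difference of 0.42 lay near that of C57 (0.04). Sod1 read 123 and 373 in ICR and 2932 and 2382 in C57, and whether strain sequence differences under its probes play a part was not tested. The ICR smoked array had the lowest median intensity and the highest 3' to 5' ratios of the 6 arrays. Left unscaled, the data gave 1787 calls, 1780 of them lower, with a median over all probe sets of -0.99.

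Within single strains, counted without a test, the number of probe sets at least 2-fold different between the smoked and control arrays was 90 in C57 (57 higher, 33 lower), 227 in DBA (51 higher, 176 lower) and 483 in ICR (208 higher, 275 lower). Cyp1a1 was among the 6 highest named in each strain. C57 also had higher Cxcl5 (2.18) and Krtdap, a keratinocyte protein (1.72), and lower Pdk4, a brake on glucose oxidation (-1.45), and Mmut, a mitochondrial mutase (-1.60). DBA had Ces1g at 2.51 and Mmp9, the neutrophil gelatinase, at -3.68. In ICR the largest named values after Cyp1a1 were Sod1 (2.45), Actb (2.20, with 0.72 at its other probe set), Arglu1 (2.11) and Zfp787 (2.11, with -0.09 at its other probe set) on the higher side. On the lower side they were Usp22 (-3.03), Sema3c, a guidance factor (-2.43), Rangrf (-2.20) and Tradd, an adaptor of the tumour necrosis factor receptor (-2.14). The named Actb probe set read only 7.31 and 31.2 in ICR, the first below the added constant. The beta-actin control probe sets, of far higher signal, went the other way in ICR, by -0.61 (3'), -1.29 (middle) and -1.89 (5'). The counts without the filter on low signal were 408, 520 and 1068, and with a stricter filter 31, 107 and 232.

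Across genes the responses of the strains were weakly and negatively related. Pearson's r between the log2 differences was -0.156 for C57 and DBA, -0.146 for C57 and ICR and -0.057 for DBA and ICR, with Spearman's rho of -0.097, -0.165 and -0.141. These are correlations across genes, which are not independent replicates, and no control array was shared between strains.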

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

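The test of whether the DBA smoked array was low in neutrophil genes and the list of immunoglobulin probe sets were chosen after the result was seen, and so were the hepatocyte, acute phase and marrow lists. Intervals given from here on come from resampling genes. They show the spread between genes on these arrays, not between animals or arrays, and genes of a list are not independent.

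The test of the difference between pairs called 53 probe sets for the DBA pair against those of C57 and ICR, and 10 for the C57 pair against the others. Each contrast sets 1 pair apart, so an unusual sample cannot be separated from a response of the strain, and on simulated data the DBA contrast called 38 unchanged probe sets. The named genes, as log2 difference of the pair minus that of the others, were in DBA Alb 6.62, Mup3 6.49, Serpina1e 2.65, Rangrf 2.62, Serpina1b 2.05, Ngp -6.97, Camp -5.21, S100a8 -4.71, S100a9 -4.11 and Ifitm6 -3.98. In C57 they were Igkv6-14 3.56, Lcn2 2.87 (-0.43 at its other probe set), Chil3 2.86, Igkv6-23 2.35, Zbtb16 -2.83 and Alb -4.79. Signal in the control probe sets, which no comparison used, set the ICR smoked array apart, with 3' to 5' ratios of 4.75 for beta-actin and 2.39 for Gapdh.

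Neutrophil genes were higher on the DBA control array than on the DBA smoked array. Scaling between arrays was argued against, since over the 10 genes tested the median difference stayed at -3.04 or lower under 3 scalings (-3.11, -3.12 and -3.04). Smoke lowering neutrophil transcripts below the level of other lungs could not be decided from 1 array. The DBA smoked array lay at -0.37 (interval between genes -1.05 to 0.07) against the mean of the 4 arrays of other strains. Bone marrow carried over with the DBA control lung stayed open too, with a marrow precursor median of 0.11 (interval -0.13 to 1.11; 7 genes, of which 4 are also in a fixed list). Single genes of the fixed neutrophil list were higher there: Elane read 107 on the DBA control array and at most 47.3 on the 5 others. Mpo, of low mean signal, read 113 against at most 10.8 at 1 probe set and 31.2 against at most 18.9 at the other. A difference in neutrophil content between the DBA lungs may be real or a feature of 1 control animal, and 1 array per group cannot tell these apart.

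Liver genes were higher on the DBA smoked array, with Alb at 1455 against 20.6 on the DBA control array and Apoa1 at 423 against 10.3. Hepatocyte RNA carried over with the lung is a candidate explanation, but the enzymes of hepatocytes gave a median of 0.60 with an interval of -0.03 to 1.12 (9 genes), which leaves it undecided. These enzymes were mixed: Cps1 (2.32) and Gnmt (0.83) were among those higher, and Fah (-0.03) and Hsd11b1 (-0.20) were lower. Fah and Hsd11b1 already read 373 and 977 on the DBA control array, where Cps1 read 15.4 and Gnmt 49.7. An acute phase response of the lung to smoke was taken to predict higher values of the acute phase list. That list gave a median of -0.25 (interval -1.16 to 0.47, 10 genes). Hp (0.11), Cp (0.15) and Lbp (-0.15) differed little and Saa3 (-1.14) was lower, while Orm1 (1.33) and Orm2 (0.82) were higher. The list as a whole thus did not rise with Alb and Apoa1. With 1 pair of arrays, neither explanation was excluded. Whether an acute phase response would raise Alb, Apoa1 or Mup3 at all was not tested. Repeating the DBA contrast without neutrophil, monocyte, B cell, liver and immunoglobulin genes (87 probe sets) gave 28 calls instead of 53.

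ICR had the most probe sets at least 2-fold different, 483, and the smoked array with the lowest signal. At a threshold of 3-fold the counts were 21 in C57, 85 in DBA and 71 in ICR, so DBA had the most. Poor RNA was taken to predict that 2 probe sets of a gene move together less in ICR than in both other strains. Across 883 genes their correlation was 0.130 in C57, 0.432 in DBA and 0.213 in ICR. ICR minus the lower of the others was 0.0827 (interval -0.0096 to 0.173), and ICR minus DBA, where a broader response of ICR lung predicted no deficit, was -0.220 (interval -0.326 to -0.102). RNA quality and a broader response cannot be told apart, since the 3 correlations each come from 1 pair of arrays. Such a correlation also depends on how large the differences of a pair are, whose SD was 0.345 in C57, 0.461 in DBA and 0.544 in ICR. It is thus no measure of RNA quality alone.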

How the results depend on the processing

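The variance prior of the shared smoke fit and the exclusion of cell type genes were chosen only after the result was seen. Where counts moved, the cause was not tested, except that leaving out probe sets leaves fewer to test. With an array or a pair left out, the same probe sets were tested, on fewer residual degrees of freedom and with a newly fitted variance prior. Of the alternatives for named genes with a test, 732 kept direction and side of the threshold, 90 lost the call, 7 gained it and none reversed. Cyp1a1 was still called in 10 of 12 alternatives (log2 3.62 to 4.56), Cyp1b1 in 5, Aldh3a1 in 7, and H2-Ea in DBA against C57 in 13 of 13. Correlations between strains stayed within 0.1. Signal near background limits the weakest genes.

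Without the filter, counts were 1 for the shared smoke effect, 66, 44 and 38 for DBA against C57, ICR against C57 and ICR against DBA, 0 and 9 for the C57 and DBA responses, and 408, 520 and 1068 for 2-fold differences within C57, DBA and ICR. With the filter at the 60th percentile, the responses gave 4 and 25 and the 2-fold differences 31, 107 and 232. A pseudocount at the 10th percentile gave 32 for the DBA response, and at the 40th percentile 41 and 219 2-fold differences in C57 and ICR. Without scaling, DBA against C57 gave 85, ICR against DBA 261, and the C57, DBA and ICR responses 0, 7 and 1787, with all-gene medians of 0.24, 0.76 and -0.99. Scaled to a common median, the C57 and DBA responses gave 36 and 8. A prior without trend gave 1 for the shared effect and 0 for the C57 response, a robust prior 2 for the C57 response, and no strain block 0 for the shared effect. The prior of the shared fit gave 0 and 9 for the C57 and DBA responses, but recovered 0 of 210 simulated changes, and excluding the cell type genes 28 for DBA. A threshold of 1.5-fold gave 561, 725 and 1877 within C57, DBA and ICR, and 3-fold 21, 85 and 71.

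Left-out pairs gave 0 to 11 calls for the shared effect and 2 to 14 called lists, and an estimated correlation 0 lists. Left-out arrays gave 102 to 298 for DBA against C57, 32 to 517 for ICR against C57 and 12 to 220 for ICR against DBA. The oesophagus list reversed without the C57 pair, to -0.52 from 0.02, and was 0.61 without the DBA pair. The responses have no residual degrees of freedom with an array left out and were not rerun that way.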

Other observations

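The test of the aryl hydrocarbon receptor in C57 against DBA was chosen only after the result was seen.

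Krt13, a keratin of stratified epithelium, read 160 and 413 on the C57 control and smoked arrays, 72.5 and 26.9 in DBA and 10.8 and 7.18 in ICR. Nnt, the mitochondrial transhydrogenase, was higher in ICR than in C57 by log2 1.82. Of the haemoglobin and erythroid genes, 8 of 8 measured had higher values on the smoked array in C57, 0 of 8 in DBA and 3 of 8 in ICR, with medians of 0.50, -0.26 and -0.08. Smooth muscle and pericyte genes were higher in 10 of 11 measured in DBA and lower in 10 of 11 in C57, with medians of 0.25 and -0.17, and cardiac muscle genes had medians of -0.24, 0.40 and -0.09 in C57, DBA and ICR. Neither list was called (adjusted p = 0.454 and 0.945).

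The larger log2 difference of Cyp1a1 in C57 (5.12) than in DBA (3.69) may reflect a more responsive aryl hydrocarbon receptor in C57. That predicts larger differences of the whole list in C57. The C57 median minus the DBA median was -0.58 (interval -1.73 to 0.68, 10 genes), which does not decide it. Of the 8 members tested 3 were called, and 4 of the 10 measured were lower with smoke in C57 and 2 in DBA. The median is thus a weak gauge of the receptor. The added constant of 8.05 also lowers the Cyp1a1 difference more in DBA, where the control array read 16.9, than in C57, where it read 58.8.

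The split of the 6 arrays into control and smoked gave 3 calls by limma and the highest of the other splits 7, and 10 splits are too few for a share under 0.05. The splits with 7 calls part the DBA pair alone, and the 3 other splits that part all 3 pairs gave fewer calls than the real one.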
